A study of Mus musculus with 6 samples.

How the data were processed

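Total RNA was extracted with TRIzol from the ear skin of 3-month-old mice and made into libraries with the NEBNext Ultra RNA kit from 3 µg of RNA per sample, per the labels' protocols. The strand setting of the counting is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart with certainty. HISAT2, HTSeq and the genome build mm10 are named in the submitters' processing notes, without versions or parameters. The authors deposited whole-number counts per gene for each library, not normalized, per the file headers and the values. FPKM values were also deposited, per the file headers, and each equals the count divided by the gene length and by 1 effective library size, which was 97.6% to 104.4% of the total count and equals the DESeq2 median-ratio size factor times the geometric mean of the totals (ratio 1). The table also holds the authors' normalized mean count (a signal value) for each group, the authors' log2 fold changes, and the authors' p-values and adjusted p-values for cKO against control, per the file headers. The test behind these columns is not named there. Gene lengths, names and coordinates were taken from the deposited table.

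Of 54532 genes in the table, 17318 passed filterByExpr and were tested, of which 14872 were protein-coding. They held 99.83% to 99.86% of the counts of each library, and every row named a gene. Total counts ranged from 17256339 to 20776539. Libraries were grouped by genotype, 3 control and 3 Ufl1 cKO. Counts were scaled by TMM and compared with the quasi-likelihood test of edgeR 4.0.16 (robust estimates, no covariates, R 4.3.3), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are the log2 fold change divided by the root of the F statistic. Levels are TMM-scaled CPM. Log2 CPM for scores and principal components used a prior count of 2. The score of a list is the mean over its measured members of log2 CPM minus the gene's mean over the 6 libraries.

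Gene lists for pigment cells, stress responses, epidermis, skin appendages, immune and other cell types were fixed before the data were examined, 38 in number. Lists with at least 3 measured genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists tested. Camera with an estimated correlation, and fry, which tests whether the genes of a list move one way without reference to other genes, were alternatives. Members were counted over all genes tested and again adjusted over the list alone. For 3 list symbols an older or other symbol of the same gene was used in the table. Genes named in the text were chosen by a rule fixed at the same time. It took up to 12 called genes per direction with a mean of at least 1 CPM in a group and all libraries of a group on one side, always Ufl1, Edn1, Ednrb and Kit, and up to 4 members of each list with the smallest p. A named gene outside this rule is said to have been chosen after its values were seen. Values of 3 genes that the rule selected are not reported here.

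Alternatives comprised RLE and upper-quartile scaling, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, non-robust estimates, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, an absolute log2 fold change of at least 1, glmTreat against a fold of 1.5, and leaving out each library in turn. The tests were run on simulated counts drawn with the means, spreads and library sizes of the comparison of cKO and control. Changes were planted in 200 of 17318 genes, all with a mean above 1 CPM. Each gene was drawn independently, so variation shared between genes was absent, and the rates may not carry over to the real libraries. edgeR recovered 6% of genes planted at 1.5-fold, 40% at 2-fold, 88% at 4-fold and 90% at 8-fold, with 15 false calls among 127. DESeq2 recovered 12%, 56%, 96% and 90% at these folds, with 46 false calls among 173. In a second simulation the ER chaperone list, raised 1.5-fold, had an adjusted p of 3.5e-21 at the preset and of 0.0554 at the estimated correlation, with 1 and 0 other lists called. Genes were drawn independently there too, so these numbers do not give the error rate of the list tests in the real libraries.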

Results

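RNA was sequenced from the ear skin of 3-month-old mice in 6 libraries. The control group held 3 libraries from mice with a floxed Ufl1 allele (heterozygous or homozygous) and no Cre. The Ufl1 cKO group held 3 libraries from mice in which both floxed alleles were combined with a Cre driven by the keratin 14 promoter, which is active in basal keratinocytes and the epithelial cells derived from them. Ufl1 is the E3 ligase that attaches the small protein UFM1 to its targets. The total count per library was 17256339, 18886858 and 20776539 in controls 1 to 3 and 18245575, 18212929 and 19050876 in cKO 1 to 3. Whole ear skin was used, so cells that never carried Cre, such as fibroblasts, melanocytes, nerve and immune cells, contributed to every value. The labels describe the libraries as samples of mice and do not state that each came from a separate animal, so p-values measure the spread between these samples. The 10 most abundant genes took between 6.12% and 8.24% of the counts, with the highest share in control 1. Mitochondrial transcripts took 4.59% of the counts in control 1 and 2.28% to 2.97% in the other 5 libraries. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 18.1. The first principal component (36.9% of the variance) set control 2 at one end and control 1 at the other and did not follow the genotype.

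The targeted gene was examined first. Ufl1 (ENSMUSG00000040359, chromosome 4, 25248600 to 25281821, mm10) was measured at 57.9, 47.0 and 46.1 CPM (counts scaled to library size) in controls 1 to 3 and at 34.9, 35.6 and 38.8 CPM in cKO 1 to 3. Every cKO library was below every control library, with means of 50.3 ± 6.58 CPM (SD, n = 3) and 36.4 ± 2.05 CPM (SD, n = 3). The log2 fold change was -0.47 (SE 0.14), which leaves 0.724 of the control level. The edgeR quasi-likelihood test gave an unadjusted p of 0.00985 and an adjusted p of 0.778 over the 17318 genes tested. A two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The count covers the whole gene, so reads from exons outside the floxed part and from cells without Cre remain in it.

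Endothelin-1, a secreted peptide that acts on melanocytes through the receptor Ednrb, is named in the title of the series, and its gene was compared next. Edn1 (ENSMUSG00000021367, chromosome 13, 42301476 to 42307990) was at 8.77, 4.23 and 3.78 CPM in controls 1 to 3 and at 8.64, 7.55 and 7.07 CPM in cKO 1 to 3. The log2 fold change was 0.48 (SE 0.34), with an unadjusted p of 0.201 and an adjusted p of 0.997 in the edgeR test and p = 0.4 in the exact permutation test, so the difference did not exceed the spread between libraries. Control 1 was above each of the cKO libraries, and the other 2 controls were below all of them. Without control 1 the log2 fold change was 0.95 (SE 0.23; unadjusted p = 0.00485, adjusted p = 0.397), and without control 3 it was 0.26 (SE 0.36). With all libraries, limma-voom with quality weights gave 0.95 (SE 0.23; unadjusted p = 0.00238, adjusted p = 0.145). In the simulation edgeR recovered 6% of genes planted at 1.5-fold and 40% at 2-fold, so a difference of this size could be missed. In the authors' deposited table the log2 fold change of Edn1 was 0.48 with an adjusted p of 0.9999. The receptor gene Ednrb had a log2 fold change of 0.23 (SE 0.38) and Kit, the receptor of stem cell factor, one of 0.39 (SE 0.32), both with an adjusted p of 0.997 in the edgeR test. Ednrb was at -0.04 without control 2 or cKO 1, at 0.08 without control 3, at 0.37 without cKO 3 and at 0.76 without control 1, and Kit at 0.08 without control 2 and at 0.64 without control 3.

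**Figure D1:**
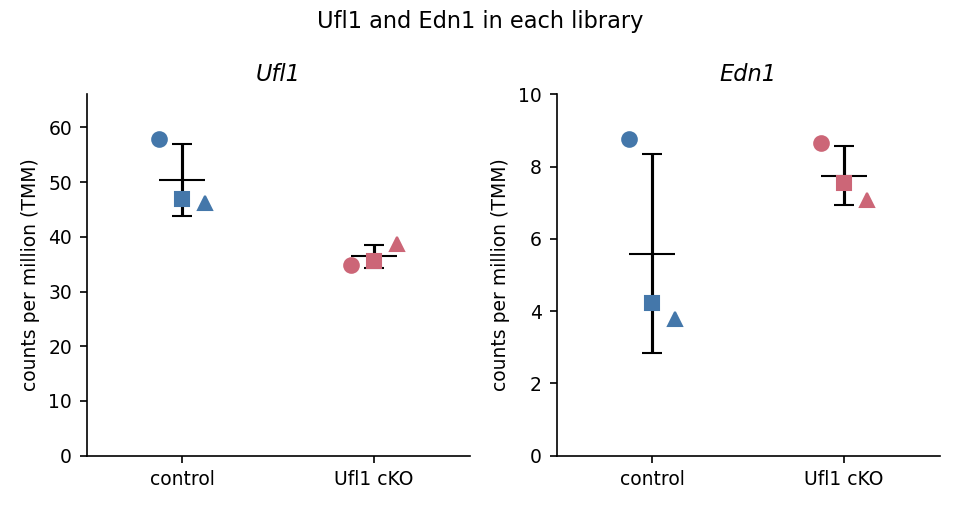
CPM values (TMM-scaled) of Ufl1 and Edn1 on linear axes from 0, one point per library, with circles, squares and triangles for replicates 1, 2 and 3. Horizontal bars are means and error bars are SD (n = 3). The cKO libraries lie between 34.9 and 38.8 for Ufl1, below all controls, and between 7.07 and 8.64 for Edn1, where control 1 lies at 8.77.

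The comparison of skin-specific knockout and control ears asked which transcripts differ when Ufl1 is deleted from keratin 14 lineage cells. No control carried Cre, so effects of the Cre transgene cannot be told apart from those of the loss of Ufl1 in any result. Two-sided edgeR testing called 2 genes higher and 1 gene lower in the cKO at an adjusted p under 0.05. Tyrp1, a melanosomal enzyme of eumelanin synthesis (chromosome 4, 80834123 to 80851719), rose from 14.6 ± 1.13 to 59.2 ± 11.8 CPM (SD, n = 3 each), a log2 fold change of 2.02 (SE 0.18). Bhlha15, a transcription factor of secretory cells also known as Mist1 (chromosome 5, 144190286 to 144194441), rose from 1, 2 and 2 counts in the controls to 38, 60 and 55 counts in the cKO, a ratio of summed counts per library total of 31.4 (exact 95% interval 13.2 to 98.0, counting error only). Serpina3j, a member of a family of secreted protease inhibitors on chromosome 12 (104314553 to 104320725), fell from 174, 82 and 252 counts to 2, 1 and 1 counts, so that the controls were 124-fold higher (exact 95% interval 48.1 to 456, counting error only). The adjusted p was 0.0295 for each of the 3 genes, and all cKO libraries lay on one side of all controls. Serpina3 genes are close paralogs, so the assignment of reads within the family is uncertain.

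The number of called genes depended on the test. At an unadjusted p under 0.05 edgeR gave 585 genes higher and 338 lower, where 866 in all would be reached by chance. DESeq2 called 67 genes higher and 24 lower on the same counts, and limma-voom called 0 in either direction (564 higher and 327 lower at an unadjusted p under 0.05). The authors' deposited table held 58 higher and 21 lower genes at an adjusted p under 0.05. These 79 included the 3 genes called by edgeR and 76 of the 91 called by DESeq2. Over the 17318 genes, log2 fold changes from edgeR and from the authors' deposited table had a Pearson r of 0.9999 across genes, which are not independent replicates. Both rest on the same 6 libraries, so neither this r nor the shared calls are independent support. Leaving out a single library other than control 2 left 0 genes called by edgeR (at an unadjusted p under 0.05, between 332 and 927 higher and between 170 and 949 lower). Without control 2 edgeR called 4 genes, of which 2, Tyrp1 and Serpina3j, were among the 3 called with all libraries. Bhlha15 was not called there. In DESeq2, in a comparison chosen after seeing the data, the 91 calls became 41 without cKO 1, 44 without cKO 3, 48 without control 3, 148 without cKO 2 and 257 without control 1.

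Genes of melanin synthesis and of melanosomes rose together in the cKO. Of 14 pigment genes measured, 14 had a positive log2 fold change, with a median of 1.92 (3.78-fold), and for 13 the cKO and control libraries did not overlap, where chance gives 10% over both directions. Tyr, the rate-limiting enzyme of melanin synthesis, went from 2.29 ± 0.464 to 13.8 ± 3.43 CPM, Dct, the dopachrome tautomerase, from 16.0 ± 4.90 to 67.3 ± 17.3 CPM, and Trpm1, a cation channel gene transcribed in melanocytes, from 4.24 ± 0.0465 to 14.8 ± 1.88 CPM (SD, n = 3 each). Their log2 fold changes were 2.59 (SE 0.28) for Tyr, 2.07 (SE 0.26) for Dct and 1.80 (SE 0.19) for Trpm1. Over all genes tested 1 of the 14 passed in edgeR (Tyrp1) and 10 passed in DESeq2, while 12 were higher when adjusted over the list alone. Tyr and Trpm1 had an adjusted p of 0.0535 in the edgeR test over all genes, and Dct one of 0.105. The list passed camera with an adjusted p of 1.8e-64 over 37 lists at a preset correlation, an adjusted p of 0.0371 with an estimated correlation, and an adjusted p of 0.0201 in fry.

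**Figure D2:**
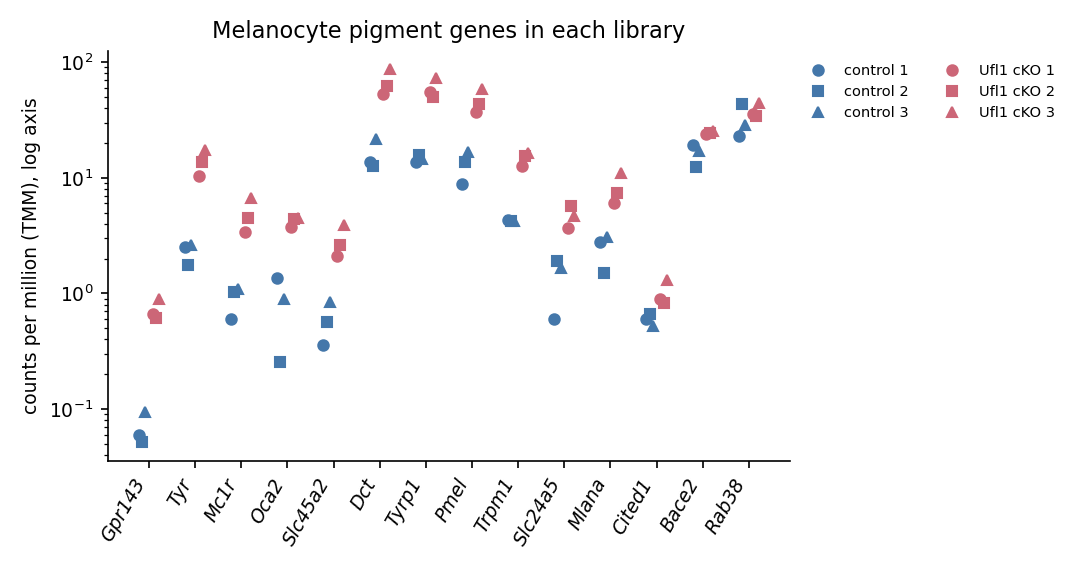
CPM values (TMM-scaled, log axis) of the 14 melanocyte pigment genes, ordered by log2 fold change, one point per library, in blue for the 3 controls and red for the 3 cKO. For 13 of the 14 genes every cKO point lies above every control point, and Rab38, named after its values were seen, is the gene where they overlap.

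Other genes of melanocytes and their environment showed smaller differences. The 8 lineage regulators and receptors had a median log2 fold change of 0.14 (camera adjusted p = 0.408; 0.06 without control 2 to 0.36 without control 1), with Pax3, a transcription factor of the melanocyte lineage, at 0.73 (SE 0.35; 0.45 without cKO 3) and Sox10, which Schwann cells also express, at -0.32 (SE 0.26; 0.05 without control 2). The 14 melanosome transport genes had a median of 0.06 (adjusted p = 0.466; 0.02 without cKO 3 to 0.10 without control 3), with Mlph at 0.51 (SE 0.34; 0.22 without control 2) and Lyst at 0.21 (SE 0.11). The 11 measured keratinocyte-derived ligands of melanocytes had a median of 0.11 (adjusted p = 0.249), which was -0.13 without control 2 and 0.39 without control 1. Among these, the log2 fold changes were -1.30 for Edn2 (SE 0.48), 0.72 for Lif (SE 0.36) and 1.47 for Nrg1 (SE 0.74), and Nrg1 was at 2.50 without control 2 and 0.84 without cKO 1, while Lif was at 0.47 in limma-voom with quality weights. In these 3 lists 0 members were called by edgeR or by DESeq2 and 0 were called when adjusted over the list alone, with 0 higher and 1 lower (Edn2) at an unadjusted p under 0.05.

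Endoplasmic reticulum (ER) chaperone genes rose in the cKO. All 22 measured genes of the list of chaperones and ER-associated degradation, targets of ATF6 and XBP1, had positive log2 fold changes, with a median of 0.59. Hspa5, the ER chaperone BiP (chromosome 2, 34771970 to 34777547), went from 324 ± 17.1 to 718 ± 36.2 CPM (SD, n = 3 each), a log2 fold change of 1.15 (SE 0.15). Sdf2l1, a component of ER chaperone complexes, was 2.82-fold higher (SE 0.23 on the log2 scale), and log2 fold changes were 0.81 (SE 0.13) for the disulfide isomerase Pdia6 and 2.39 (SE 0.42) for Derl3, a factor of ER-associated degradation. None of the 22 passed edgeR over all genes, while 9 passed in DESeq2, 16 had an unadjusted p under 0.05 in edgeR and 16 were higher when adjusted over the list alone. The list passed camera at the preset correlation (adjusted p = 2.0e-34), with an estimated correlation (adjusted p = 0.0371) and in fry (adjusted p = 0.00508). The list score, the mean log2 CPM relative to all libraries, lay between -0.34 and -0.30 in the controls and between 0.27 and 0.36 in the cKO.

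**Figure D3:**
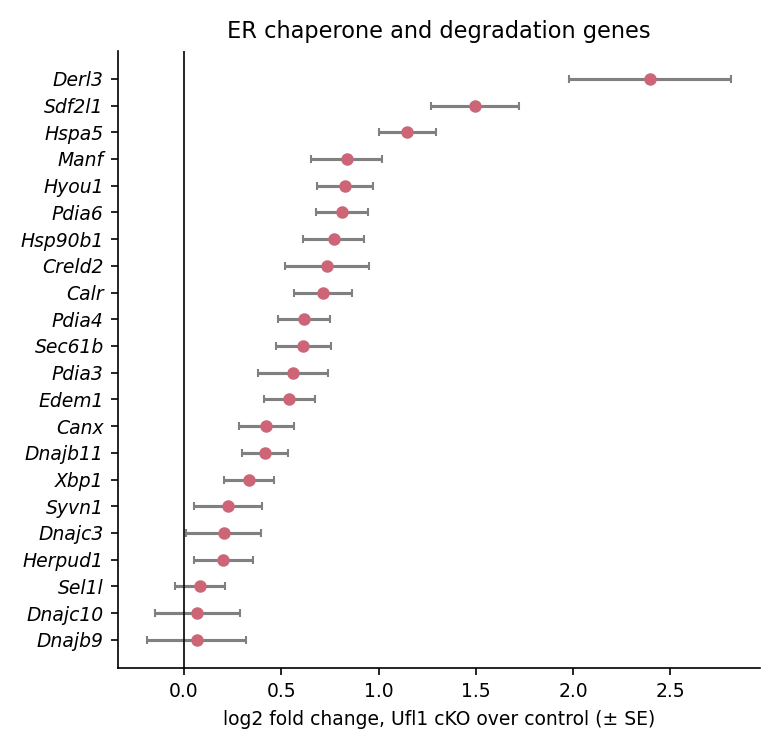
Log2 fold changes (cKO over control, horizontal axis) of the 22 ER chaperone and degradation genes, with bars for the standard error from edgeR (n = 3 per group). All 22 points lie to the right of 0, with Derl3 at 2.39 and Dnajb9, named after its values were seen, at 0.07.

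Targets of the integrated stress response, controlled by ATF4 and CHOP, had a median log2 fold change of 0.21 over 24 genes, and 19 were positive. Slc7a11, the cystine transporter subunit, was at 1.38 (SE 0.36), Slc7a5, a neutral amino acid transporter, at 0.69 (SE 0.18) and Mthfd2, of mitochondrial folate metabolism, at 0.64 (SE 0.22). Camera gave an adjusted p of 8.5e-05 at the preset correlation and an adjusted p of 0.111 with an estimated correlation, and fry an adjusted p of 0.0322. No member passed edgeR over all genes or when adjusted over the list alone, 3 were higher at an unadjusted p under 0.05, and 1 (Slc7a11) passed DESeq2. The p53 targets had a median of 0.20, with the cell cycle inhibitor Cdkn1a at 0.51 (SE 0.14), Psrc1 at 1.14 (SE 0.34) and Zmat3 at 0.43 (SE 0.14). Their adjusted p was 0.00316 in camera, 0.272 with an estimated correlation and 0.0895 in fry. The ufmylation machinery had a median of 0.12 over 8 genes (camera adjusted p = 0.648; 0.08 without cKO 3 to 0.19 without control 2). Its conjugating enzyme Ufc1 was at 0.25 (SE 0.12).

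Interferon-stimulated, alarmin and cytokine genes had high values in some cKO libraries. The 21 interferon-stimulated genes had a median log2 fold change of 1.45 and were all positive, with Oas2 at 1.96 (SE 0.47), Oas1a at 2.04 (SE 0.57) and Oasl2 at 2.49 (SE 0.77). The chemokine gene Cxcl10 was at 5.02, 1.94 and 79.9 CPM in cKO 1 to 3 and at 0.619 to 2.03 CPM in the controls. The 21 stress keratin and alarmin genes had a median of 1.47, and Krt16, a keratin of wounded and inflamed epidermis, was at 358, 51.8 and 40.4 CPM in cKO 1 to 3 and at 3.17 to 14.3 CPM in the controls. Sprr1b was at 3.31 (SE 0.83), Slpi at 2.24 (SE 0.60) and Krt17 at 0.87 (SE 0.23), and without cKO 1 Sprr1b was at 1.77 and Slpi at 1.17. The 10 measured inflammatory cytokine genes had a median of 1.38, with Ccl4 at 2.93 (SE 0.77) and Ccl2 at 1.60 (SE 0.56; 0.81 without cKO 3). All 3 lists passed camera at the preset correlation and not with an estimated one, where the adjusted p was 0.425, 0.425 and 0.511, nor in fry, where it was 0.572 for each. No member of the 3 lists passed edgeR over all genes, 2, 2 and 1 passed DESeq2, and 0, 6 and 0 were higher when adjusted over the list alone.

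These 3 lists differed between libraries of one group. The interferon score was 1.90 in cKO 3, 0.59 in cKO 1 and -0.49 in cKO 2, which lay below control 1 (-0.08). The alarmin score was 2.10 in cKO 1 and 0.11 and 0.09 in the others, next to -0.03 in control 1, and the median of the list was 0.31 without cKO 1. Without cKO 3 the median of the interferon-stimulated genes was 0.71, while that of the cytokine genes was 0.79 without cKO 1 and 2.09 without cKO 2. Neutrophil markers scored 1.66 in cKO 1 and -0.97 to 0.11 in the other libraries, and T cell markers 1.14 in cKO 3 and -0.52 to -0.04 in the others. Control 2 had the lowest score in all 3 lists.

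**Figure D4:**
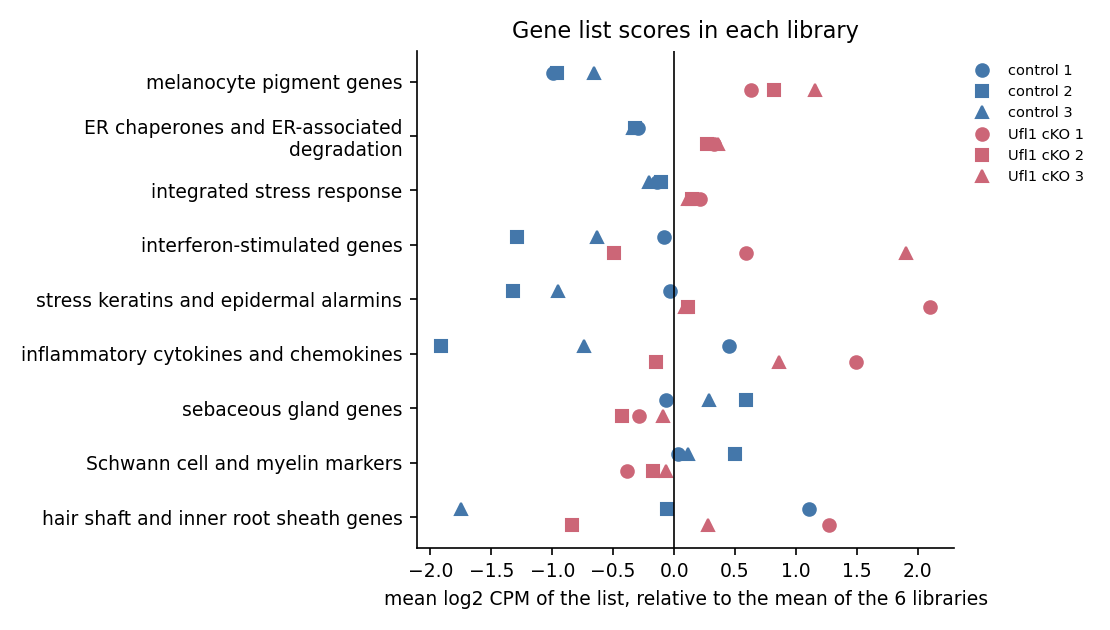
Scores of 9 gene lists in each library (mean log2 CPM of the measured members relative to the mean of the 6 libraries, horizontal axis), in blue for controls and red for cKO. The pigment and ER lists separate the groups, with pigment scores of -0.99 to -0.66 in the controls and 0.63 to 1.16 in the cKO, while hair shaft genes range from -1.75 in control 3 to 1.27 in cKO 1.

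Genes of the sebaceous gland list had mostly negative log2 fold changes. Elovl5, a fatty acid elongase, went from 224 ± 16.3 to 109 ± 8.46 CPM (SD, n = 3 each), a log2 fold change of -1.03 (SE 0.13), and Scd3, a stearoyl-CoA desaturase of sebaceous glands, had a log2 fold change of -3.66 (SE 0.63). Both were lower when adjusted over the list alone and in DESeq2 (2 of 15 genes each), and 0 members passed edgeR over all genes. Of the 15 genes 13 were negative, with a median of -0.29 (-0.51 without control 1), while the melanocortin receptor gene Mc5r was at 0.48 (SE 0.20). The camera adjusted p was 1.4e-07, and with an estimated correlation the adjusted p was 0.425. Schwann cell and myelin markers had a median of -0.52 over 8 genes, with Mbp at -0.54 (SE 0.18), Ncmap at -0.51 (SE 0.14) and Prx at -0.46 (SE 0.19). Their camera adjusted p was 1.6e-05, and the adjusted p with an estimated correlation was 0.274.

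Epidermal layers were compared through lists of basal and suprabasal genes. The 13 basal keratinocyte genes had a median log2 fold change of -0.16 (camera adjusted p = 0.201). Without control 2 the median was 0.14, and without control 1 it was -0.37 and the list passed as lower (adjusted p = 0.00114). Krt15, a keratin of basal and follicle stem cells, was at 445, 1375 and 730 CPM in controls 1 to 3 and at 213, 247 and 374 CPM in cKO 1 to 3, with an adjusted p of 0.650 in edgeR and of 0.0103 in DESeq2. The 24 suprabasal and cornified envelope genes had a median of 0.16, with Flg (filaggrin) at 0.95 (SE 0.39; 1.63 without control 2, where its adjusted p was 0.0232), Cdsn at 0.74 (SE 0.26; 0.47 without cKO 1) and Casp14 at 0.96 (SE 0.36). Their camera adjusted p was 0.00462, and with an estimated correlation the adjusted p was 0.666. The list did not pass without cKO 1 (median -0.01), control 1 (0.06) or control 3 (0.10), and the median was 0.46 without control 2 and 0.29 without cKO 2. Hair shaft and inner root sheath genes had a median of 0.24 (camera adjusted p = 0.452) and varied more between libraries of a group than between groups, with scores of 1.11, -0.06 and -1.75 in controls 1 to 3 and of 1.27, -0.84 and 0.28 in cKO 1 to 3. The list passed as higher without control 1 (median 1.18), without cKO 2 (0.59) or with the replicate number as a block (0.39, adjusted p = 0.0482), and its median was -0.22 without control 3 and -0.49 without cKO 1.

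Markers of other cell types were compared in the same way. Endothelial (median 0.00, camera adjusted p = 0.897), cartilage (0.01, adjusted p = 0.769), skeletal muscle (-0.10, adjusted p = 0.249) and mast cell markers (0.19, adjusted p = 0.0923) did not pass, though the mast cell list passed as higher on limma-voom values (0.22, adjusted p = 0.0498). Fibroblast (0.27), macrophage (0.40), Langerhans and dendritic cell (0.53), erythrocyte (0.67) and adipocyte markers (-0.29) passed camera at the preset correlation, with an adjusted p between 0.000230 and 0.0153, but all 5 had an adjusted p of 0.666 with an estimated correlation. In the Langerhans and dendritic cell list 8 of 9 genes were positive, while Cd207, a Langerhans cell marker, was at -0.53 (SE 0.31). Without control 1 the Langerhans and adipocyte lists did not pass (medians 0.64 and -0.19), the mast cell list passed as higher (0.43), and the fibroblast, macrophage and erythrocyte medians were 0.49, 0.65 and 1.37. Without control 2 the fibroblast (0.04), macrophage (0.16), Langerhans (0.42) and erythrocyte lists (0.35) did not pass, and the cartilage list passed as lower (-0.17). The adipocyte median was then -0.56 and the mast cell median 0.07. Without control 3 the adipocyte (-0.10) and erythrocyte lists (0.45) did not pass and the muscle list passed as lower (-0.25). The macrophage median was 0.24 without cKO 1. Without cKO 2 the erythrocyte list did not pass (0.35), the muscle list passed as lower (-0.42), and the adipocyte median was -0.45. Without cKO 3 the Langerhans (0.05), adipocyte (-0.16) and erythrocyte lists (0.56) did not pass. The muscle median was 0.32 without control 1 and 0.18 without cKO 3. Neutrophil markers had a median of 2.05 over 5 genes (adjusted p = 0.1003), with Cxcr2 at 2.31 (SE 0.72) and Mmp9 at 2.10 (SE 0.80). In contrast Mpo, the myeloperoxidase of immature neutrophils, was at -3.55 (SE 0.70). It lay near the floor, at 1.37, 0.825 and 1.23 CPM in controls 1 to 3 and at 0.167, 0.111 and 0 CPM in cKO 1 to 3. When adjusted over the list alone 4 of the 5 neutrophil genes were higher and 1 (Mpo) lower. Without cKO 1 the neutrophil median was 0.58, with Cxcr2 at 0.99 (SE 0.41) and Mmp9 at 0.50 (SE 0.42), and the list passed as higher without cKO 2 (2.08), without cKO 3 (1.98) or with the replicate number as a block (1.61, adjusted p = 0.000602). T cell markers had a median of 0.70 (adjusted p = 0.0995), with Trbc2 at 0.78 (SE 0.20) and the gamma delta T cell gene Trdc at -0.72 (SE 0.28; -1.10 without cKO 3). Without cKO 3 the T cell median was -0.47, and the list passed as higher without cKO 1 (0.77), without cKO 2 (0.89) or with no filter on low counts (0.74, adjusted p = 0.00813). Y-linked transcripts were present in all 6 libraries, and the sex-linked list did not differ (median -0.06, adjusted p = 0.741).

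The remaining lists held no gene called by edgeR or by DESeq2. NF-kappaB feedback targets (median 0.32) and cytosolic ribosomal proteins (0.13) passed camera with an adjusted p of 0.000909 and 0.00411, and had an adjusted p of 0.561 and 0.676 with an estimated correlation. The NF-kappaB list did not pass without cKO 3 (median 0.12) and had a median of 0.19 without cKO 1, and the ribosomal list did not pass without control 3 (0.05) or cKO 3 (0.08) and had a median of 0.21 without control 2. The lists of immediate early genes (0.04, adjusted p = 0.617), hypoxia targets (-0.01, adjusted p = 0.720), NRF2 targets (-0.08, adjusted p = 0.316), autophagy and lysosome genes (0.03, adjusted p = 0.916), oxidative phosphorylation genes (-0.08, adjusted p = 0.105), cell cycle genes (0.11, adjusted p = 0.0995) and circadian clock genes (-0.22, adjusted p = 0.0995) did not pass. The cell cycle list passed as higher without control 2 (0.47), without cKO 2 (0.27) or with no filter on low counts (0.11, adjusted p = 0.0444). Its median was -0.07 without control 1, -0.05 without cKO 3 and -0.01 without control 3. The oxidative phosphorylation list passed as lower without control 3 (-0.16) or cKO 2 (-0.14), with a median of -0.02 without control 1. The clock list passed as lower without control 1 (-0.21) or cKO 2 (-0.29), with a median of -0.12 without control 2 or control 3. At an unadjusted p under 0.05, edgeR found Hlf at -0.46 (SE 0.13), Egln3 at 0.71 (SE 0.21), Pdk1 at -0.39 (SE 0.14) and Gclc at -0.36 (SE 0.12). In the NF-kappaB list 2 more genes were higher at this threshold. Over all genes tested 923 fell under it, where 866 would be reached by chance, so such single genes carry little weight. Over all 37 lists 14 were called higher and 3 lower at the preset correlation, 2 with an estimated correlation and 3 in fry. Splits of the 6 libraries that mixed the genotypes gave 12 to 19 lists at the preset correlation. A pass at the preset correlation alone, also with a library left out, therefore carries little weight. Of the lists fixed, the B cell list had too few measured genes for a test.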

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

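The added alternative, DESeq2 with a library left out, was chosen after seeing the data; all others were set before. The log2 fold changes of Ufl1 (-0.53 to -0.36 over the alternatives) and Edn1 (0.26 to 0.95) and the median of the pigment genes (1.80 to 2.02) kept their direction and their side of the threshold under every alternative run. For the lists, runs with a library left out, RLE scaling, no filter, the block or limma-voom values used the preset correlation. The estimated correlation and fry were run for the 2 genotypes on all 6 libraries only, so their stability was not tested. The counts of called genes, 2 higher and 1 lower in edgeR, were the same with RLE or upper-quartile scaling, the filter of 1 CPM in 3 libraries, non-robust estimates, a log2 fold change of at least 1 and glmTreat. They were 18 higher and 7 lower with no filter on low counts, 67 and 24 with DESeq2, and 29 and 10 with limma-voom and quality weights. They were 0 and 0 with limma-voom and with limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), where 500 and 490 genes were higher and 307 and 309 lower at an unadjusted p under 0.05. The cause was not tested. Leaving out 1 library, which takes a sample from a group, gave 0 to 2 genes higher and 0 to 2 lower in edgeR (0 and 0 except without control 2), and 41 (without cKO 1) to 257 (without control 1) calls in DESeq2, with 44 without cKO 3, 48 without control 3, 128 without control 2 and 148 without cKO 2. Of the 4 edgeR calls without control 2, 2 were among the main 3 genes, and Bhlha15 was not called. With the replicate number as a block edgeR called 10 genes higher and 2 lower. The deviations of same-numbered libraries from their group means had correlations of 0.22, -0.04 and -0.04, and only number 1 correlated best with its own number, so the numbers were not taken as pairs. Of 37 lists, 17 passed camera at the preset correlation, 2 with an estimated one and 3 in fry (the cause was not tested), and 13 to 23 without 1 library. The list of Langerhans and dendritic cell markers turned from higher to lower without cKO 3 (median 0.046, camera direction down, not past the threshold; 0.046 to 0.75 without 1 library), and that of cartilage markers turned to lower, past the threshold, without control 2 (median -0.17; -0.17 to 0.19 without 1 library). Medians of other lists near 0 or not past the threshold also changed sign, among them those of T cell markers (-0.47 to 0.89) and basal keratinocyte genes (-0.37 to 0.14). Among 989 values of 66 named genes under the alternatives, 911 kept their side of the threshold, 59 gained and 19 lost a call, and 0 turned direction past the threshold. Short of the threshold 5 values of 3 genes (Ednrb, Sox10 and Dnajb9, the last named after its values were seen) changed sign. The authors' table has no column of calls, so an adjusted p under 0.05 was used and the comparison of both was not run. In the simulation, with the depth, spread and group size of these libraries but genes drawn independently, edgeR recovered 6% of genes changed by 1.5-fold.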

Other observations

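The tests of hair follicles, other cell types, melanocyte number, individual ears and the Serpina3 family, and 2 gene lists of the secretory pathway, were chosen after the results were seen; the comparison with other splits of the libraries was set before its result. Beyond the chaperones, most genes of protein entry into the ER and of export from it had positive log2 fold changes. In a list of 28 genes of the translocon, signal peptidase and oligosaccharyltransferase, 27 were positive with a median of 0.31, and in a list of 25 genes of ER to Golgi transport 24 were positive with a median of 0.23. Members named after their values were seen were Sec61g at 0.66 (SE 0.12), Ssr4 at 0.58 (SE 0.12) and the cargo receptor gene Lman1 at 0.63 (SE 0.11), all called by DESeq2 and not by edgeR. Because these lists were built after such calls were seen, they were tested on the members that neither DESeq2 nor a fixed list had singled out. The 23 translocon genes had a median of 0.26 with 22 positive (camera p = 0.0714 with an estimated correlation, fry p = 0.0226), and the 24 transport genes a median of 0.23 with 23 positive (camera p = 0.0325, fry p = 0.0132). None of these p-values is adjusted for the other lists, so a rise of these genes as a group remains open.

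Of the 91 genes called by DESeq2, 62 were in no fixed list. Chosen after their values were seen, they included Serpinb3a, an epidermal protease inhibitor gene, at a log2 fold change of 2.68 (SE 0.35), Nucb2 at 0.90 (SE 0.13) and P4hb, a disulfide isomerase gene, at 0.79 (SE 0.16), and on the lower side Serpina3b at -3.59 (SE 0.40), Ces1d, a carboxylesterase gene, at 0.498 of the control level and Hsd3b6, of steroid metabolism, at -1.81 (SE 0.34). In edgeR the adjusted p of these 6 genes was between 0.0535 and 0.464. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3 genes in edgeR and 2 of the 10 splits gave as many, with 3 as the highest of the other splits. DESeq2 gave 91 genes, 3 splits gave as many, and the highest other had 157. That split put control 1, cKO 1 and cKO 2 on one side. Whether these samples share a structure apart from genotype was not tested. Camera at the preset correlation gave 17 lists and 4 splits gave as many. The other splits had 12 to 19 lists. With an estimated correlation 1 split, the real one, gave 2 lists and the highest other 0.

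The pigment genes rose with a difference in score of 1.74 (SE 0.19) between the groups. Growing hair follicles hold melanocytes, so a larger share of such follicles could raise pigment genes. With the hair shaft score as a term in the fit, the difference was 1.79 (SE 0.18, 3 residual degrees of freedom). The slope on the hair score was -0.10 (SE 0.08). These values argue against a larger share of growing follicles as the whole cause. A lower share of the main cell types would raise markers of the other types alike, but the medians of 12 such lists lay between -0.52 (Schwann cells) and 2.05 (neutrophils, with an SD over members of 2.52), against 1.92 for the pigment genes, and 10 of the 12 were below the pigment genes by more than the spread of their members. More melanocytes and more pigment gene transcripts per melanocyte cannot be told apart, because the lineage genes (median 0.14, and 0.06 to 0.36 without 1 library) are also transcribed in nerve, mast and other cells of the skin. Either could itself be an effect of the genotype.

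The interferon, alarmin and cytokine lists may reflect inflammation in individual ears. The range among the 3 cKO libraries was 1.78, 1.31 and 1.11 times the difference between the groups in the 3 lists, the lowest ratio being 1.11, and the range among the controls 0.903, 0.845 and 1.61 times that difference. For the ER list the range among the cKO was 0.145 times the difference between the groups, and for the pigment genes 0.301 times. The score was above every control in 2 of 3 cKO libraries for the interferon and cytokine lists and in 3 of 3 for the alarmin list, with an exact permutation p of 0.2, 0.2 and 0.1. Inflammation that follows from the deletion in some ears and inflammation unrelated to it remain open.

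Serpina3j and Serpina3b lie in 1 cluster on chromosome 12, and together went from 61.6 to 4.43 CPM, a change of -57.2 (SE 12.7). Reads moved to paralogs could produce such a loss. The other 6 tested members gained 38.9 CPM (SE 50.2), a spread too wide to exclude or to show a transfer of that size. A strain variant at the cluster is a candidate explanation too. Of 27 other tested genes within 1 Mb, 1 had an unadjusted p under 0.05, but a variant acting on this pair alone would leave the neighbours at their level, so this explanation and an effect of the genotype cannot be told apart.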
